A study of Rattus norvegicus with 12 samples.

How the data were processed

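Poly(A) RNA from rat jejunum and liver was sequenced as paired reads, per the labels' protocols, in 3 libraries of each tissue from saline rats and 3 from antibiotic-treated rats. The submitters' processing notes name CASAVA 1.4, HISAT2 2.0.5 and DESeq2 1.20.0. They give neither the genome build nor the tool that counted reads, nor whether counting used strand, so overlapping and antisense genes cannot be told apart. Each tissue has its own table, with 21568 genes in jejunum and 18703 in liver.

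The count columns, per the file headers, hold the authors' normalized signal: tested on the values, each is a whole number of reads divided by 1 factor per library. All values (100%) came back whole within 0.01 reads, so reads were recovered. The authors also deposited FPKM, which is the same normalized count divided by gene length and 1 constant per library. The log2 fold changes and the p-values with their adjusted values are the authors' own comparison, per the file headers. An adjusted p under 0.05 is given for 1772 jejunal genes (943 higher, 829 lower) and 3079 liver genes (1703 higher, 1376 lower) in the deposited comparison. Of the limma calls below, 249 of 249 in jejunum and 2099 of 2121 in liver are in the authors' deposited table at that threshold.

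All computing used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. The choices in this paragraph and the next were fixed before the data were examined, except where said. The plan was an edgeR test on counts, with limma as the fallback where the values are not whole counts. As deposited values were normalized, the fallback was used: limma (trend, robust) on log2 of the normalized count plus 1, in genes with a mean of at least 1, within each tissue, with Benjamini-Hochberg adjustment and a threshold of 0.05. That left 19450 jejunal and 16540 liver genes. The tissue difference was tested with edgeR's quasi-likelihood test (TMM, filterByExpr) on recovered reads of annotated genes, 16531 of which have the same identifier in both tables. Loci not in the annotation were left out of that test, since 910 of their identifiers occur in both tables and 0 of these have the same start.

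The 57 gene lists, 31 of pathways and 26 of cell type markers, hold 986 symbols, of which 861 matched in jejunum and 825 in liver, 4 of them in each tissue by an older symbol. Lists were tested with camera with a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over all 57. These ran on the values used for limma rather than on log2 CPM with a prior count of 2, as first planned, and the latter was kept as an alternative. The tissue difference used cameraPR. Genes named are, per tissue, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and a gene symbol that is not a placeholder. Added to these are the drug and bile acid genes fixed in advance and, of each list described, the members with the smallest p. For the tissue difference up to 4 genes per direction were named.

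Alternatives were no filter, a filter of 1 CPM, pseudocounts of 0.1 and 5, replicate number as a block, scaling by library totals, edgeR, DESeq2, limma-voom, a spread pooled over 12 libraries and each library left out in turn. Chosen after seeing the data were TMM scaling, edgeR with TMM, limma for the tissue difference and a correction for gene length. That correction subtracted from each library a lowess trend (span 0.3) of its deviations on log gene length, fitted in genes with a mean of at least 50. Comparisons of library measures used two-sided exact permutation tests.

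Recovered reads were 18322008, 14592126 and 18224818 in the jejunal wild-type libraries and 16298045, 15980618 and 16415356 in the jejunal antibiotics libraries. In liver they were 15017775, 15083018 and 16182483 in wild type and 17903583, 18146538 and 19318616 with antibiotics. A count of 0 was given a floor of 3 reads per library, which covers counting error only. The tests were tested on simulated data: with 100 genes changed by log2 1 and 100 by log2 2, limma recovered 10% and 66% of them in jejunum, and 24% and 93% in liver. The test of the tissue difference recovered 2% and 44%. Limma called 2 unchanged genes in jejunum and 0 in liver. With a trend by gene length added to the simulated antibiotics libraries it called 12 and 30, and 3 and 4 after the correction for gene length. Fold changes in the data follow gene length, as given below, so the limma calls may hold such false ones. No pair of libraries was found to be a duplicate.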

Results

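RNA sequencing of poly(A) RNA measured gene expression in the jejunum and liver of Wistar Han rats. Rats received either saline, called wild type in the labels, or a mixture of antibiotics by gavage for 2 weeks. The mixture held ampicillin, neomycin and metronidazole at 20 g/L each, vancomycin at 10 g/L and the antifungal amphotericin B at 0.2 g/L, given at 5 mL/kg. There were 3 libraries in each of the 4 groups, 12 in all. Recovered reads per library ranged from 14592126 to 18322008 in jejunum and from 15017775 to 19318616 in liver. Values below are normalized counts, as mean ± SD with n = 3 per group, and fold changes are log2 of antibiotics over wild type. The genome build behind the coordinates is not stated. The series title sets the question of how loss of the gut microbiota changes host genes that handle drugs.

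The first comparison asked which jejunal genes differed with antibiotics. Genes of muscle stood among the largest rises. Myocd, a coactivator of smooth muscle transcription, rose from 33.4 ± 13.7 to 322.7 ± 104 (log2 fold change 3.26, SE 0.43, adjusted p = 0.0147). Kcnmb1, a potassium channel subunit of smooth muscle, rose from 126.7 ± 68.5 to 893 ± 63.4, a log2 change of 2.96 with SE 0.39 and adjusted p = 0.0147. Among the largest falls, Zp2, a glycoprotein of the egg coat (ENSRNOG00000057989, chromosome 1, 189899892 to 189911650), was at 205.7 ± 43.5 in wild type and at 0 in all 3 antibiotics libraries. This was at least 78.9-fold lower, against a floor of 3 reads per library that covers counting error only (limma adjusted p = 0.00497). Cyp2e1, an enzyme that oxidises ethanol and other small molecules (ENSRNOG00000012458, chromosome 1, 213511874 to 213535542), fell from 191.2 ± 168 to 13.7 ± 7.83 (log2 fold change −3.55, SE 0.70, adjusted p = 0.0402).

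The other jejunal genes with the largest rises were Mn1, Tent5b, the muscarinic receptor gene Chrm2, the bicarbonate transporter gene Slc4a7, the adenylate cyclase gene Adcy1 and the collagen receptor gene Itga1. Their log2 fold changes ran from 2.96 for Itga1 to 3.80 for Mn1. The other largest falls were Taf15 (−3.55), the neutrophil enzyme gene Mpo (−3.09), Fkbp2 (−2.83), Mgst1 (−2.66), the carboxylesterase gene Ces2g (−2.60) and Anp32a (−2.53). Each of these genes separated all 3 libraries of one group from all 3 of the other. Wild-type library 3 had the fewest reads outside mitochondrial genes. Its normalized counts were 4.30 for Mn1, 8.60 for Slc4a7 and 10.8 for Chrm2, so these values rest on few reads.

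Of the jejunal cell type lists outside the epithelium, smooth muscle, fibroblast and enteric neuron markers were higher with antibiotics. Endothelium (median −0.02) and macrophage markers (0.10) did not pass (camera adjusted p = 0.913 and 0.787), and adipocyte markers, given below, were lower. All 10 smooth muscle markers measured were above 0, with a median log2 fold change of 1.405 (camera adjusted p = 0.000233). Of these, 1 passed over all genes tested and 10 when adjusted over the list alone. Lmod1 rose from 1198 ± 542 to 3646 ± 299, and Myh11, smooth muscle myosin, was at 19043 ± 12389.9 and 56708 ± 1859. All 8 fibroblast markers were above 0 (median 1.07, camera adjusted p = 0.0131), 0 passed over all genes by limma and 6 when adjusted over the list alone. For instance, Col6a1 was at 991 ± 540 and 2957 ± 644, and Pdgfra at 579.5 ± 269 and 1244 ± 41.0. The fibroblast list lost its call without wild-type library 2 (median 0.56, adjusted p = 0.0647). Of 9 markers of enteric neurons and glia, 8 were above 0 (median 0.96, camera adjusted p = 0.0284), 0 passed over all genes by limma and 4 adjusted over the list alone. Ret was at 195.6 ± 106 and 585 ± 78.2, and Elavl4 at 140.3 ± 90.7 and 368.6 ± 61.9. The neuron and glia list lost its call without wild-type library 2 (adjusted p = 0.229) or 3 (adjusted p = 0.0644), with library totals (median 1.45, adjusted p = 0.0824) and with a spread pooled over 12 libraries (0.71, 0.419). For all 3 lists, adjusted p = 0.623 with an estimated correlation. Wild-type library 1 stood near the antibiotics libraries, with deviations of 0.27, 0.19 and 0.41 for smooth muscle, fibroblast and neuron markers. Wild-type libraries 2 and 3 were at −1.12 and −1.18, −1.31 and −0.44, and −1.14 and −0.51. The antibiotics libraries ran from 0.61 to 0.75, 0.37 to 0.62 and 0.28 to 0.49. The rises therefore rest mostly on wild-type libraries 2 and 3.

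Cell cycle, Paneth cell and goblet cell lists were lower in jejunum. Of 31 cell cycle genes, 30 were below 0 (median −0.90, camera adjusted p = 3.96e-05), yet 0 passed over all genes by limma and 1, Birc5, when adjusted over the list alone. Birc5, a gene of dividing cells, was at 190.2 ± 134 and 28.5 ± 13.7. All 8 Paneth cell markers were below 0 (median −2.28, camera adjusted p = 0.00122), with 0 past the limma threshold over all genes and 5 adjusted over the list alone. The defensin RatNP-3b was at 5909.5 ± 3573 and 1032 ± 685, and the antimicrobial phospholipase Pla2g2a at 4695 ± 5256 and 753 ± 194. Defensin genes are near-identical copies, so their counts are uncertain. Wild-type library 2 stood apart for these lists, with deviations of 1.48 for cell cycle genes and 2.39 for Paneth cell markers against −0.08 and −0.13, and 0.46 and 0.40, in wild-type libraries 1 and 3. Without it the cell cycle median was −0.44 and the Paneth median −1.55 (adjusted p = 0.0108 and 0.00709). Of 10 goblet cell markers, 8 were below 0 (median −0.85, camera adjusted p = 0.0477), and 0 passed limma either way. The goblet cell call ended without wild-type library 2 or 3 or antibiotics library 1 or 3 (adjusted p = 0.207, 0.101, 0.158 and 0.0691), and with the correction for gene length (adjusted p = 0.0940), where the median was −0.90. The median was −0.51 without wild-type library 2, −1.39 without wild-type library 1 and −1.37 without antibiotics library 2. Enterocyte markers had a median of −0.54 and did not pass (camera adjusted p = 0.0673). Intestinal stem cell markers did not pass either (median −1.26, camera adjusted p = 0.115). Of 6 measured, 1, Smoc2, rose over all genes, and 4 fell and 1 rose when adjusted over the list alone. Enteroendocrine (median −0.68) and tuft cell markers (0.22) did not pass (camera adjusted p = 0.308 and 0.976). With an estimated correlation, adjusted p = 0.623 for the cell cycle, Paneth and goblet lists.

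Metabolic lists also fell in jejunum. Of 24 glutathione S-transferases, 21 were below 0 (median −0.85, camera adjusted p = 0.000404, and −0.52 with adjusted p = 0.0114 after the correction for gene length). Of these, 1 fell over all genes and 7 when adjusted over the list alone. Mgst1 fell from 4415 ± 1139 to 749 ± 368. Of 30 xenobiotic receptors and liver transcription factors, 27 were below 0 (median −0.56, camera adjusted p = 0.000233). The factors Cebpa (2738 ± 204 to 540.5 ± 138) and Cebpb (1230 ± 281 to 482 ± 51.9) fell over all genes, and 6 fell and 1 rose when adjusted over the list alone. Of 43 other phase I enzymes, 31 were below 0 (median −0.75, camera adjusted p = 0.00264), and 3 fell over all genes and over the list alone, namely Ces2g, Ephx1 and Akr7a2. Without wild-type library 3 the phase I list lost its call (median −0.39, adjusted p = 0.0919). Members of the glutathione S-transferase family share sequence, so their counts are uncertain. For these 3 lists, adjusted p = 0.623 with an estimated correlation. Adipocyte markers, given below, fell more in the same libraries (median −2.25). How far a difference in fat between the pieces bears on these lists was not tested.

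Further jejunal lists past 0.05 with camera were adipocyte markers (median −2.25, adjusted p = 4.80e-05), NRF2 targets (−0.56, 0.0156), pericentral hepatocyte markers (−1.06, 0.0189), lipogenesis (−0.54, 0.0309), erythroid markers (−0.88, 0.0341), pancreatic acinar markers (−0.96, 0.0416) and other conjugating enzymes (−0.76, 0.0421). Each had adjusted p = 0.623 with an estimated correlation. All 9 adipocyte markers were below 0, 0 passed limma over all genes and 8 when adjusted over the list alone. Fabp4 was at 11424 ± 8289 and 1007 ± 633, and the hormone gene Lep at 835.8 ± 790 and 69.4 ± 74.2. In the lipogenesis list, the regulator Srebf1 (1379 ± 525 to 357.4 ± 50.4) and Agpat2 (1037 ± 315 to 273.3 ± 80.6) fell. Whether these falls follow that of the adipocyte markers was not tested. Fatty acid oxidation genes had a median of −0.46 (camera adjusted p = 0.0153 and adjusted p = 0.623 with an estimated correlation), which turned to 0.04 when libraries were scaled by their totals alone. With the same scaling the NRF2 median was −0.06 and did not pass (adjusted p = 0.105). That scaling moved the median of all jejunal genes to 0.51, and both lists still lay below it. Acinar markers did not pass with DESeq2 (adjusted p = 0.157), edgeR and RLE (0.0651), edgeR and TMM (0.0692), limma-voom (0.0818), a spread pooled over 12 libraries (0.119) or no filter, where the median was −0.42. Leaving out 1 library ended several of these calls. Without wild-type library 3, adjusted p = 0.0919 for NRF2 targets, 0.0655 for lipogenesis, 0.176 for erythroid markers and for fatty acid oxidation, and 0.206 for conjugating enzymes. Without wild-type library 1 it was 0.122 for lipogenesis and 0.158 for erythroid markers, and without antibiotics library 1 it was 0.103 for acinar markers. Without antibiotics library 2 it was 0.0668 for erythroid markers and 0.0573 for conjugating enzymes. Without antibiotics library 3 it was 0.0644 for lipogenesis, 0.0960 for conjugating enzymes and 0.0818 for fatty acid oxidation. The correction for gene length, described below, ended the calls of acinar markers (median −0.59, adjusted p = 0.0963), erythroid markers (−0.69, 0.112) and conjugating enzymes (−0.67, 0.0615). Medians also moved without single libraries, to −0.20 for lipogenesis and −0.49 for conjugating enzymes without antibiotics library 3. Without wild-type library 3 the median of fatty acid oxidation was −0.29, and −0.31 with the correction. Without wild-type library 2 that of erythroid markers was −1.62.

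Few of the drug and bile acid genes fixed in advance passed in jejunum, as the plot of these genes shows. Besides the fall in Cyp2e1, the values were 537 ± 376 and 955.7 ± 644 for Cyp2b1, 58.0 ± 41.7 and 15.2 ± 7.35 for Cyp2d2, 672.6 ± 218 and 353.8 ± 237 for Nr1i2, which encodes the receptor PXR, and 298.7 ± 30.7 and 232.8 ± 119 for Nr1i3, which encodes CAR. None of these 4 passed (limma adjusted p = 0.421, 0.272, 0.189 and 0.469). Cyp1a2, Cyp2c11 and Cyp3a23/3a1 lay under the filter on mean value, and Cyp7a1, Cyp8b1, Cyp3a2 and Abcb1a were not listed for jejunum. Among 22 genes of CYP families 1 to 3, Cyp1b1 rose (405.6 ± 298 to 1748 ± 277, adjusted p = 0.0392) and Cyp2e1 fell, with the same counts adjusted over the list alone. That list as a whole did not pass (median −0.04, camera adjusted p = 0.720). Of 23 ABC transporters, Abcc9 rose (405.2 ± 177 to 1299 ± 147) and 7 rose when adjusted over the list alone, while the list did not pass (camera adjusted p = 0.114) except with edgeR and RLE, edgeR and TMM, or DESeq2 (adjusted p = 0.0459, 0.0455 and 0.0159).

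**Figure D1:**
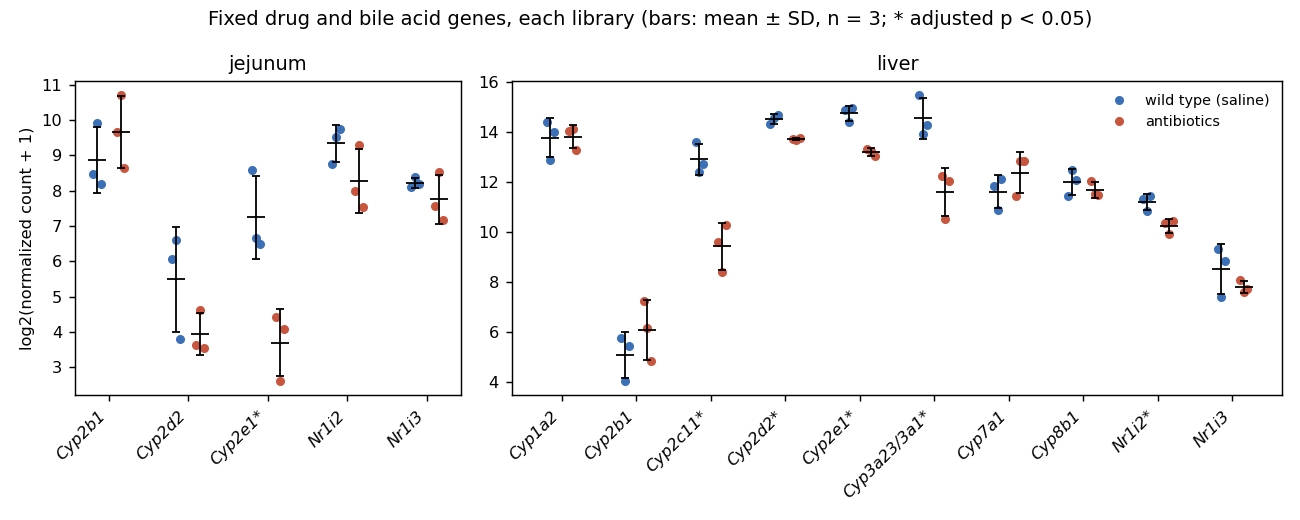
Log2 of normalized count plus 1 for the drug and bile acid genes fixed in advance, in jejunum and liver. Points are libraries, bars are mean ± SD of 3 libraries on the log2 scale, and an asterisk marks a limma adjusted p under 0.05. In liver, Cyp2c11, Cyp2d2, Cyp2e1, Cyp3a23/3a1 and Nr1i2 were lower in all 3 antibiotics libraries than in all 3 wild-type libraries.

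In all, 249 of 19450 jejunal genes passed limma at an adjusted p of 0.05, 148 higher and 101 lower, and each of the 249 separated the groups. Of all genes tested, 27.9% separated them, where chance gives 10%. The count changed with each library left out: it was 1902, 108 and 62 without wild-type libraries 1, 2 and 3, and 1, 3 and 1 without antibiotics libraries 1, 2 and 3. Zp2 was called in each of those 6 fits, and without antibiotics library 2 the other genes called were Taf15 and Fkbp2. Without antibiotics libraries 1, 2 and 3, 2683, 3617 and 2652 genes had an unadjusted limma p under 0.05. Each of the 6 fits also has 1 library fewer, and the part of that in these counts was not tested. Scaling by library totals alone, which shifted the median gene by 0.51 on the log2 scale, gave 55 higher and 4 lower. The 4 lower were Zp2, Lep, AABR07007675.1 and LOC103690108, of which all but Zp2 lie outside the rule for named genes and were chosen after their values were seen. After a correction for gene length 24 genes passed, all among the 249. Cyp2e1 no longer passed under that correction, though its log2 fold change was −3.54 after it and −3.55 before (adjusted p = 0.0688, in a range of 0.0524 to 0.178 over the alternatives that ended its call).

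The second comparison asked the same of liver. Enzymes and secreted proteins typical of male rat liver were among the largest falls. Cyp2c11, the main male-specific P450 (ENSRNOG00000052810, chromosome 1, 257970345 to 258004434), fell from 8199 ± 3753 to 785 ± 450 (log2 fold change −3.48, SE 0.51, adjusted p = 0.0116). Cyp3a23/3a1, a drug-oxidising P450 (ENSRNOG00000032560, chromosome 12, 11655402 to 11733136), fell from 26966 ± 16241 to 3505 ± 1799.8, a log2 change of −2.96 with SE 0.56 and adjusted p = 0.0212. The major urinary protein genes Mup4 (454.3 ± 268 to 3.41 ± 4.11) and Mup5 (51628 ± 36033 to 5848 ± 2973) fell by 6.96 and 3.02 on the log2 scale. Scube1, a secreted protein gene (ENSRNOG00000010617, chromosome 7, 124501988 to 124620703), had the largest rise among the genes eligible to be named, from 8.65 ± 6.46 to 463.7 ± 204 (log2 fold change 5.89, SE 0.71, adjusted p = 0.00760). Cyp2c11, Cyp3a23/3a1 and the Mup genes each have near-identical relatives, so their counts are uncertain.

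Others among the largest rises in liver were the bicarbonate transporter gene Slc4a4 (4.27), Prkar2a (4.12), the cytokine receptor gene Il13ra1 (4.10), Edem3, which acts in disposal of misfolded glycoproteins (3.81), Fam8a1 (3.65) and Slc35e1 (3.50). The other largest falls were Tstd1 (−2.84), the mitochondrial locus AY172581.20 (−2.84), the respiratory chain gene Mt-nd4 (−2.76) and the globin gene Hbb-bs (−2.66), whose reads may be split with other globin copies. Without wild-type library 3, Scube1 was the only 1 of the 16 genes with the largest changes to pass.

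Among the drug and bile acid genes fixed in advance, Cyp2e1 fell in liver from 27921 ± 5739.7 to 9459 ± 933 (log2 fold change −1.54, adjusted p = 0.00842). Cyp2d2 fell from 23768 ± 2996 to 13457 ± 318 (−0.81, adjusted p = 0.0381), and Nr1i2, which encodes the receptor PXR, from 2371 ± 492 to 1231 ± 223 (−0.94, adjusted p = 0.0290). Cyp1a2 (15426 ± 7238 and 14921 ± 4297), Cyp2b1 (37.0 ± 19.6 and 83.4 ± 62.7) and Nr1i3 (423.2 ± 239 and 223.3 ± 39.1) did not pass. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (3344 ± 1317 and 5836 ± 2646), and Cyp8b1 (4261 ± 1449.95 and 3326 ± 753) did not pass either (limma adjusted p = 0.294 and 0.475). Without wild-type library 3 none of the 5 falls passed: adjusted p = 0.0616 for Cyp2e1 and Cyp2c11, 0.0803 for Cyp3a23/3a1, 0.149 for Cyp2d2 and 0.132 for Nr1i2. Their log2 fold changes in that fit were −1.43 for Cyp2e1, −3.58 for Cyp2c11, −3.10 for Cyp3a23/3a1, −0.73 for Cyp2d2 and −0.82 for Nr1i2. Without any 1 antibiotics library Cyp2d2 and Nr1i2 did not pass, with adjusted p of 0.0990, 0.134 and 0.104 for Cyp2d2 and of 0.0756, 0.117 and 0.0658 for Nr1i2. Nr1i2 was also lost without wild-type library 1 (adjusted p = 0.0674), and Cyp3a23/3a1 without antibiotics library 3 (adjusted p = 0.0606). Cyp2d2 did not pass with the correction for gene length, with library totals or with a spread pooled over 12 libraries (adjusted p = 0.0584, 0.106 and 0.378). Its log2 fold changes in these were −0.65, −0.66 and −0.81. Library totals and the pooled spread also ended the call of Nr1i2 (adjusted p = 0.0554 and 0.142), and the pooled spread that of Cyp2e1 (adjusted p = 0.0869). Nr1i3 passed without wild-type library 2 (adjusted p = 0.00168). Cyp3a2 and Abcb1a were not listed for liver.

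Glutathione S-transferases and male-biased genes fell as lists in liver. Of 22 glutathione S-transferases, 21 were below 0 (median −0.96, camera adjusted p = 1.98e-06), with 7 lower over all genes and 18 when adjusted over the list alone. Gsta1 fell from 15255 ± 6523 to 3216 ± 255, and Gstm7 from 9497 ± 2357 to 2736 ± 1231. All 10 male-biased liver genes were below 0 (median −1.50, camera adjusted p = 3.20e-05), with 5 lower over all genes and 8 over the list alone. One of them, Sult1e1, an estrogen sulfotransferase, fell from 27650.1 ± 5972 to 9167 ± 1383. Of 9 female-biased liver genes, 5 were above 0 and 4 below (median 0.59), with 1 higher over all genes. The female-biased list did not pass (camera adjusted p = 0.799). Of 30 genes of CYP families 1 to 3, 7 fell and 1 rose over all genes, and 15 fell and 4 rose when adjusted over the list alone. The CYP list itself did not pass (median −0.59, camera adjusted p = 0.0551), though it passed under several alternatives. They included fry (adjusted p = 0.0489), a pseudocount of 5 (0.0441), library totals (0.0363), DESeq2 (0.00474), the pooled spread (0.0231), the correction for gene length (0.0475) and leaving out antibiotics library 1 (0.0409). Of 44 other phase I enzymes 8 fell, among them Ces1d (2612 ± 825 to 657 ± 72.1) and Pon3, and 2 rose, and this list did not pass (camera adjusted p = 0.120). When adjusted over the list alone, 10 of them fell and 3 rose. Sulfotransferases (median −0.75, camera adjusted p = 0.0613), other conjugating enzymes (−0.49, 0.120) and UDP-glucuronosyltransferases (−0.17, 0.843) did not pass. Among alternatives, sulfotransferases passed with no filter (adjusted p = 0.0381), a pseudocount of 5 (0.0441), library totals (0.0335), DESeq2 (0.00906) and fry (0.0489). Conjugating enzymes passed with fry (adjusted p = 0.0489), and phase I enzymes with DESeq2 (adjusted p = 0.00684). The male-biased list did not pass with fry (adjusted p = 0.0696), while the glutathione S-transferase list did (0.0489). With an estimated correlation, adjusted p = 0.624 for the glutathione S-transferase, male-biased, CYP, sulfotransferase and conjugating lists.

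Lists of secreted plasma proteins and of protein folding rose in liver. Of 23 acute phase protein genes, 21 were above 0 (median 1.03, camera adjusted p = 5.37e-06), with 9 higher over all genes and 10 adjusted over the list alone. The metalloreductase gene Steap4 rose from 855 ± 170 to 3643 ± 743, the transcription factor gene Stat3 from 1401 ± 297 to 4277 ± 855, and the endotoxin-binding protein gene Lbp from 7153 ± 1956 to 21710.3 ± 3689.8. Of 23 unfolded protein response genes, 20 were above 0 (median 0.76, camera adjusted p = 3.20e-05), with 11 higher over all genes and 13 adjusted over the list alone. Creld2 rose from 423 ± 40.4 to 1459 ± 101, Edem1 from 653.7 ± 181 to 3397 ± 514 and the chaperone gene Hyou1 from 1025 ± 366 to 4059 ± 367. Of 25 cholesterol synthesis genes, 21 were above 0 (median 0.62, camera adjusted p = 0.0161), with 5 higher over all genes, and 7 higher and 2 lower over the list alone. Lss rose from 277.5 ± 178 to 1193 ± 423. The cholesterol list lost its call without wild-type library 1 (median 0.21, adjusted p = 0.152) or antibiotics library 2 (adjusted p = 0.0658), and with the correction for gene length (median 0.49, adjusted p = 0.0531). With an estimated correlation, adjusted p = 0.624 for the first 2 lists and adjusted p = 0.801 for cholesterol synthesis. With fry the first 2 lists passed (adjusted p = 0.0489 each) and cholesterol synthesis did not (0.351).

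Lists of mitochondria, amino acid metabolism, periportal hepatocytes, erythroid cells, macrophages and the interferon response fell in liver. All 13 mitochondrially encoded genes were below 0 (median −1.99, camera adjusted p = 1.04e-05), with 6 lower over all genes and 13 over the list alone. Deviations for that list were 2.00, −0.30 and 1.31 in the wild-type libraries and −0.59, −1.18 and −1.24 in the antibiotics libraries. Of 27 genes of gluconeogenesis and amino acid breakdown 7 fell, such as Prodh1 and Otc, while Asns, which makes asparagine, rose (median −0.60, camera adjusted p = 0.00585). When adjusted over the list alone, 11 fell and 3 rose. Of 9 periportal markers 3 fell (median −0.52, camera adjusted p = 0.0158), and 4 over the list alone. Of 6 erythroid markers 3 fell (median −1.50, camera adjusted p = 0.00567), and 6 over the list alone, with Hba-a2 from 11300.4 ± 4810.2 to 3133 ± 982. Of 14 macrophage markers 6 fell, and 7 over the list alone, such as Aif1 (646.8 ± 244 to 200.9 ± 31.9) and Cd68 (median −0.59, camera adjusted p = 0.00797). Of 58 interferon response genes 13 fell and 6 rose, and 16 fell and 7 rose over the list alone (median −0.37, camera adjusted p = 0.0440). Cxcl9 fell from 185.4 ± 49.7 to 47.9 ± 12.8, and Isg15 from 254.9 ± 124 to 57.4 ± 16.5. With an estimated correlation, adjusted p = 0.624 for the amino acid, periportal and erythroid lists and adjusted p = 0.628 for the other 3. None of these lists passed with fry. Its adjusted p was 0.127 for mitochondrial genes, 0.0714 for amino acid breakdown, 0.0696 for periportal and 0.0963 for erythroid markers. For macrophage markers it was 0.123 and for the interferon response 0.131. Without wild-type library 2 the amino acid, periportal and interferon lists lost their calls (adjusted p = 0.0602, 0.0932 and 0.123), and the interferon list also without antibiotics library 1 or 2 (adjusted p = 0.0789 and 0.128). The interferon median was −0.22 without antibiotics library 1, and the periportal median −0.78 without antibiotics library 3. The macrophage median was −0.38 both without wild-type library 3 and with the correction for gene length.

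**Figure D2:**
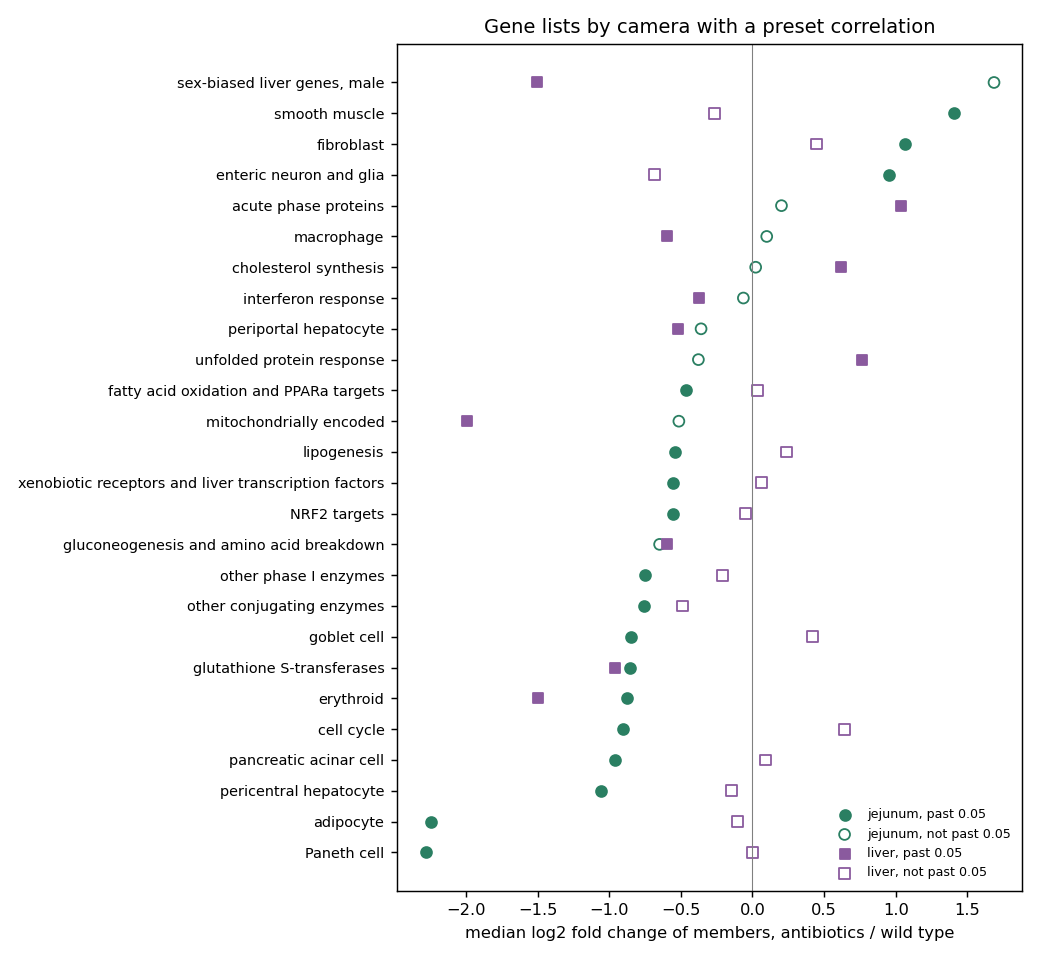
Median log2 fold change, antibiotics over wild type, of the members of each gene list past 0.05 in at least 1 tissue by camera with a preset correlation. Circles are jejunum and squares are liver, filled where the list passed. Smooth muscle stood at 1.405 in jejunum and acute phase proteins at 1.03 in liver. The jejunal median of fatty acid oxidation genes turned to 0.04 when libraries were scaled by their totals alone, which moved that of all jejunal genes to 0.51.

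In all, 2121 of 16540 liver genes passed limma, 1312 higher and 809 lower, and each of the 2121 separated the groups. Of all genes tested, 37.8% separated them, where chance gives 10%. The count was 918, 4416 and 74 without wild-type libraries 1, 2 and 3, and 482, 528 and 379 without antibiotics libraries 1, 2 and 3. With library totals alone, which shifted the median gene by 0.14 on the log2 scale, 1116 genes were higher and 412 lower. After a correction for gene length 1607 passed, of which 1334 were among the 2121. Over both tissues, 0 of 57 lists passed camera with an estimated correlation, with 1 list at an unadjusted p under 0.05 in jejunum and 0 in liver. The rotation test fry called 0 lists in jejunum, with 9 at an unadjusted p under 0.05, and 8 in liver.

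Fold changes followed gene length in both tissues. In jejunum the median log2 fold change went from −0.71 in genes of up to 500 bases to 0.66 in genes over 8000 bases, and in liver from −0.70 to 0.43. Spearman's rho of gene length with each library's deviation was between −0.30 and −0.18 in the jejunal wild-type libraries and between 0.26 and 0.34 in the antibiotics libraries. In liver it was between −0.39 and −0.19 in wild type and between 0.17 and 0.49 with antibiotics. Both differences had a two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows. These rho values are across genes, which are not independent replicates. Mitochondrial genes took 15.8 ± 9.28% of liver reads in wild type and 4.003 ± 0.445% with antibiotics (two-sided exact permutation p = 0.1). In jejunum they took 56.8 ± 27.5% and 51.6 ± 13.0% (two-sided exact permutation p = 0.9).

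**Figure D3:**
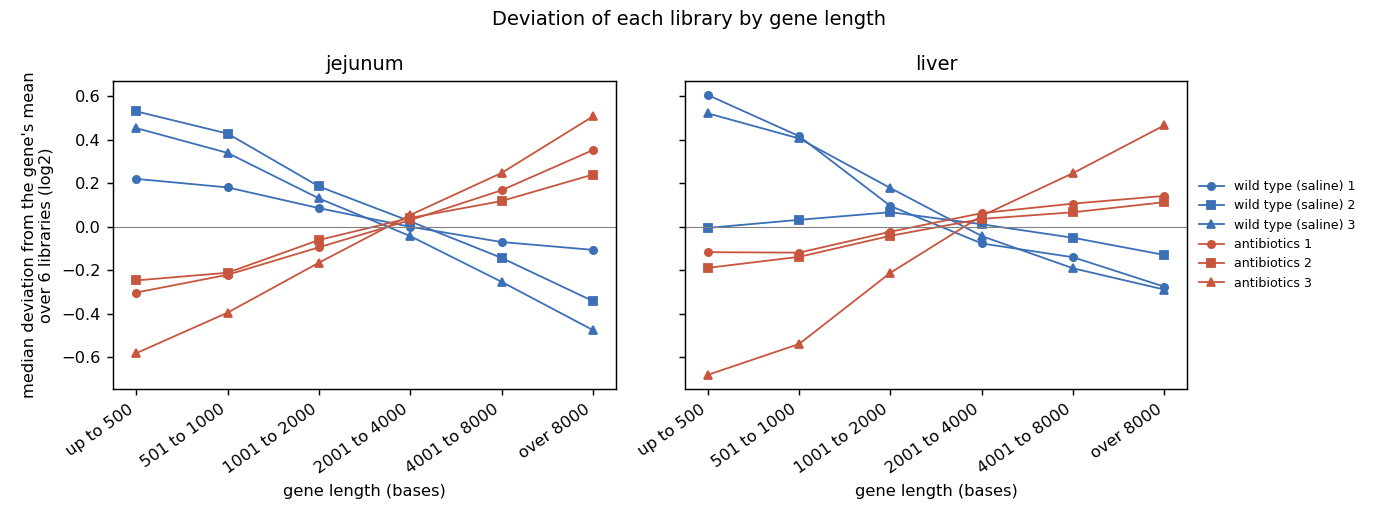
Median deviation (log2) of each library from the gene's mean over the 6 libraries of its tissue, by gene length in bases. Lines are libraries. In both tissues wild-type libraries are lowest and antibiotics libraries highest in genes over 8000 bases, where the median log2 fold change was 0.66 in jejunum and 0.43 in liver.

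Effects in the tissues overlapped in part. Among 14721 genes tested in both, 45 were called in both, 25 higher in both and 20 lower in both, with 0 opposite by limma. Independent lists would share 10.3 higher, 4.33 lower and 13.6 opposite. Slc4a7 (3.22 in jejunum and 2.72 in liver), Itga1 (2.96 and 1.87) and Scube1 (2.74 and 5.89) rose in both tissues. Cyp2e1 (−3.55 and −1.54) and Fkbp2 (−2.83 and −1.05) fell in both. Across genes, which are not independent replicates, the fold changes had Pearson's r of 0.24 and Spearman's rho of 0.26. After the correction for gene length, 1 gene was called in both tissues and r was 0.22. Only 24 jejunal genes passed after it, which limits the overlap, and the number that independent lists would share was not computed. Nothing in the labels says whether jejunum and liver libraries came from the same rats.

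A direct test asked where the effect of antibiotics differed between tissues. Genes of the endoplasmic reticulum were among those called. For Creld2, normalized counts were 310.7 ± 89.6 and 159.8 ± 34.2 in jejunum and 423 ± 40.4 and 1459 ± 101 in liver (liver effect minus jejunum effect 2.69, SE 0.33, edgeR adjusted p = 0.00911). The folding factor gene Erp29 differed by 2.26 (adjusted p = 0.0386), with 790.5 ± 186 and 191.2 ± 46.1 in jejunum and 930.5 ± 212 and 1133 ± 98.4 in liver. Spsb4 differed by 4.42 (adjusted p = 0.00911), Kif12 by 3.33 (adjusted p = 0.0386) and Idua, a lysosomal enzyme gene, by −1.92 (adjusted p = 0.0452). In all, 8 of 14187 genes passed, 6 with a higher effect in liver and 2 with a lower one. The other 3, Gucy2c (5.60), Wars1 (2.11) and Abcc8 (−4.75), lie outside the rule for named genes and were chosen after their values were seen.

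By the same test on lists, the effect was higher in liver than in jejunum for cell cycle genes (median difference 1.72, cameraPR adjusted p = 3.25e-07) and the unfolded protein response (1.01, adjusted p = 1.10e-06). It was also higher for lipogenesis (1.14), the list of xenobiotic receptors and liver transcription factors (0.68) and adipocyte markers (1.99), each with adjusted p = 0.00247. It was lower for smooth muscle markers (−1.46, adjusted p = 0.00150). The receptor genes Nr1i2 and Nr1i3 were not called for a difference between tissues. Their log2 fold changes by limma were −1.07 and −0.47 in jejunum and −0.94 and −0.73 in liver. Male-biased liver genes also passed (−4.47, adjusted p = 0.0396), but Cyp4a2, Hao2 and Mup5 were at 0 in all 3 jejunal wild-type libraries, so this value rests on few jejunal reads. It was −1.61 without jejunal antibiotics library 2, and no difference between tissues is read from it. The male-biased call ended without jejunal wild-type library 1, 2 or 3 (adjusted p = 0.189, 0.118 and 0.0599), jejunal antibiotics library 1 or 2 (adjusted p = 0.119 and 0.217), liver wild-type library 1 (adjusted p = 0.0615) or liver antibiotics library 2 (adjusted p = 0.0530). An estimated correlation cannot be had from gene statistics alone, so these list tests rest on the preset one. The count of genes was 834, 95, 4, 2, 4 and 2 without jejunal wild-type libraries 1, 2 and 3 and antibiotics libraries 1, 2 and 3. Without the liver libraries in the same order it was 0, 592, 0, 5, 2 and 3, and edgeR gave 2141 and 2214 genes at an unadjusted p under 0.05 where it called 0. DESeq2 called 852 genes and limma-voom 45.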

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

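Tests chosen after the result was seen were those of mitochondrial reads, of the share of epithelium, of the muscle layer, of the share of hepatocytes and of Y-linked genes. Tests of 2 explanations, gut wall and hepatocytes, were also changed after their outcome was seen. The comparison of smooth muscle with endothelium was first set as the test of more gut wall in the antibiotics pieces, and it argued against that explanation. It was then kept for the share of epithelium, and a new test was written for the muscle layer. The share of hepatocytes was first tested by comparing hepatocyte markers with male-biased genes, whose difference of 1.02 was within the SD over members of 2.04 and decided nothing. Later the muscle layer test was made to need an estimated correlation as well, and the hepatocyte test, by then a comparison of stellate cells with macrophages, to hold after the correction for length, which it did not. The comparison of erythroid with endothelium markers was chosen last, from values already seen.

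The effect of antibiotics differed between jejunum and liver for 8 genes in a direct test with edgeR, which is what marked these for a closer look. Liver effect minus jejunum effect (log2) was 4.42 for Spsb4, 3.33 for Kif12, 2.69 for Creld2, 2.26 for Erp29 and −1.92 for Idua. Of 100 drawn from the 200 splits of the libraries within tissues, 4 called as many genes, the real one included. That share is under the 0.05 set in advance, but near it and from a draw, so chance is not excluded. Labels were reassigned in each tissue separately. Some splits therefore turn an effect shared by both tissues into a difference between them, and do not stand for chance alone. The highest of the other splits called 209 genes against 8 in the real one. Whether such splits or a structure of the samples gave this was not tested.

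Within tissues the splits are too few for a share under 0.05. In jejunum the real split called 249 genes and the highest of the other 9 called 0 by limma, with 198 to 1725 genes at an unadjusted p under 0.05 in those 9. Only limma was run on these splits. In liver the real split called 2121 and the highest other 1. In each tissue 1 of 10 splits, the real one, called as many genes.

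The first pattern is that fold changes follow gene length in both tissues. A shift in the share of reads taken by mitochondrial genes is argued against in jejunum. There that share differed by −5.25 percentage points (antibiotics minus wild type), and the wild-type range of 26.8% to 80.7% encloses the antibiotics range of 38.7% to 64.8%, while the length trend of each library separates the groups. In liver it stays open: the share differed by −11.8 percentage points, and its ranges of 6.42% to 25.0% in wild type and 3.60% to 4.48% with antibiotics separate the groups as the trend does. A bias of the libraries by transcript length met its test, set on genes expressed in 1 tissue alone. There Spearman's rho of fold change and length was 0.316 in 433 jejunal genes and 0.273 in 151 liver genes. These genes come from the same libraries, where rho was 0.376 and 0.368 over all genes with a mean of at least 50. The test therefore does not separate a bias of the libraries from another cause that follows length. Such a bias may come from RNA quality or library preparation, on which the labels give no values per sample. Unspliced RNA stays open. At a given gene length the partial rho with genomic span was 0.168 in jejunum and 0.179 in liver, less than the 0.231 and 0.216 with length at a given span, so unspliced RNA and long transcripts cannot be told apart here. No biological explanation of the length trend was tested.

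The second pattern is that smooth muscle, fibroblast and enteric neuron lists were higher in jejunum with antibiotics. Length bias as the whole cause is argued against, since the median of the 3 lists' medians was 0.91 after the correction for length and 1.07 before it. A lower share of epithelium alone would raise every other cell type alike. Smooth muscle markers exceeded endothelium markers by 1.42, beyond an SD over members of 0.341, and by 1.69 after the correction. This argues against it as the only change. That SD is over genes and not over libraries, where endothelium deviations ran from −0.96 to 0.55. A lower share of epithelium beside another change stays open. More of the muscle layer in the antibiotics pieces stays open. Enterocyte markers had a median of −0.74 after the correction (camera adjusted p = 0.0209), but did not pass before it (camera adjusted p = 0.0673, and adjusted p = 0.736 with an estimated correlation). Lower enterocyte markers are also what fewer epithelial cells would give, so the test does not separate the layers. The site of the piece is open too: antibiotics library 3 held the ileal marker Fabp6 at 9108, against 14.4 to 119 in the other 5. Without that library the smooth muscle, fibroblast and neuron medians were 1.33, 1.04 and 0.93 (adjusted p = 0.000684, 0.0232 and 0.0464). Adipocyte markers differed as well, with a median of −2.25 (adjusted p = 0.623 with an estimated correlation). Their deviations were 2.20, −0.41 and 1.92 in the wild-type libraries and −0.54, −1.34 and −1.83 in the antibiotics libraries. Whether the pieces held less fat was not tested. A change of the gut itself with antibiotics was not tested.

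The third pattern is that male-biased genes, glutathione S-transferases and single drug-metabolising genes such as Cyp2e1 were lower in liver with antibiotics. The lists of CYP families, other phase I enzymes, sulfotransferases, UDP-glucuronosyltransferases and other conjugating enzymes did not pass camera, although some alternatives called all of these but the UDP-glucuronosyltransferases. For the CYP list adjusted p = 0.0475 with the correction for length. After the correction for length the male-biased median was −1.35, against −1.50 before, which argues against length bias as the whole cause. Female animals in the antibiotics group are argued against by the Y-linked genes Eif2s3y and Kdm5d, whose lowest count in an antibiotics liver library was 182 reads. A lower share of hepatocytes as the whole cause would raise markers of other cells alike, and these moved apart. Erythroid markers lay below endothelium markers, with a difference of −1.70 before the correction for length and −1.06 after it, beyond an SD over members of 0.213. By the test as written this argues against that cause. A change in erythroid cells alone would give the same difference, so it does not decide. Stellate cell markers exceeded macrophage markers by 1.38 before the correction and 0.84 after it, on either side of the SD over members of 0.941, and decide nothing. Hepatocyte markers had a median of −0.48 (camera adjusted p = 0.344), with 3 lower and 1 higher over all genes. A lower share of hepatocytes stays open. Reads shared between close relatives such as the Cyp2c, Cyp3a and Mup genes were not tested. Loss of the microbiota and a direct action of the antibiotics on the liver both stay open, and the design does not separate them.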

How the results depend on the processing

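Chosen after the data were seen were TMM scaling, edgeR with TMM, limma for the tissue difference and the correction for gene length, and the tests of these settings are reported with the planned ones. The lists were planned on log2 CPM and run on the values used for limma instead, once the values were known to be normalized. On log2 CPM the jejunal lists of conjugating enzymes and lipogenesis did not pass (adjusted p = 0.0635 and 0.0821). Except where stated, the cause was not tested.

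In jejunum the main count was 249 (148 higher, 101 lower). It was 160 (95 and 65) with a pseudocount of 0.1, 59 (55 and 4) with library totals, which moved the median gene to 0.51, and 125 (61 and 64) with edgeR and RLE. DESeq2 gave 1772 (943 and 829), a spread pooled over 12 libraries 1521 (813 and 708), edgeR with TMM 97 (39 and 58) and the length correction 24 (15 and 9). Without 1 library it ranged from 1 to 1902 (higher 0 to 1258, lower 1 to 644). It was 0 higher by limma without antibiotics library 1, 2 or 3, where 2683, 3617 and 2652 genes had an unadjusted p under 0.05. No other tool was run on those 5 libraries. The count stayed within 1.5 times with no filter (287), a filter of 1 CPM (189), a pseudocount of 5 (330), limma-voom (295) and TMM scaling (239).

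In liver the main count was 2121 (1312 higher, 809 lower), and without 1 library it ranged from 74 to 4416 (higher 54 to 2519, lower 20 to 1897). Genes lower numbered 412 with library totals, 1376 with DESeq2, 410 of 1399 in all with a spread pooled over 12 libraries and 507 with the length correction. The other settings without a library left out were within 1.5 times.

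For the tissue difference the main count was 8 (6 and 2). DESeq2 gave 852 (444 and 408), limma-voom 45 (31 and 14), the length correction 41 (28 and 13) and limma on the deposited values 84 (51 and 33). Without 1 library it ranged from 0 to 834 (higher effect in liver 0 to 394, lower 0 to 485). The 0 came from edgeR without liver wild-type library 1 or 3, with 2141 and 2214 genes at an unadjusted p under 0.05, and no other tool was run there. It was 8 with RLE and with a filter of 1 CPM.

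Replicate numbers were not taken to pair libraries, as the same-number correlations were not all above 0.1. For jejunum wild type against antibiotics they were 0.24, 0.28 and 0.0868, where pairs of different number ran from −0.232 to 0.034. Liver same-number values were 0.118, −0.149 and −0.189. Between jejunum and liver the same-number values were −0.0245, 0.0254 and 0.00653 in wild type and 0.0997, 0.108 and 0.225 with antibiotics. With antibiotics, pairs of different number ran from −0.165 to 0.0894. In jejunum, and between tissues with antibiotics, every same-number value was above all others, so pairing by number stays open there. With replicate number as a block, jejunum had 1625 genes (897 higher, 728 lower), liver 1779, and the tissue difference 5 (5 and 0, where edgeR without the block gave 2 lower and DESeq2 408). At an unadjusted p under 0.05 that block gave 2719. With the block, liver Cyp2d2 had adjusted p = 0.0816, the liver CYP and sulfotransferase lists 0.0486 each and the jejunal acinar list 0.0549.

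Further settings ended calls of jejunal lists. For lipogenesis these were a filter of 1 CPM (adjusted p = 0.0875), edgeR with RLE (0.0598) or TMM (0.0668) and limma-voom (0.0531). For conjugating enzymes they were no filter (0.0869), a pseudocount of 0.1 (0.0540), limma-voom (0.0751) and the pooled spread (0.0844). For goblet cells they were a pseudocount of 0.1 (0.0553), TMM scaling (0.0509) and the pooled spread (0.246). Limma-voom ended that of erythroid markers (0.0609), and no filter that of pericentral markers (0.0538).

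The jejunal list of fatty acid oxidation genes changed sign with library totals, to a median of 0.0396 (adjusted p = 0.0915). That scaling moved the median of all jejunal genes to 0.51, and the list still lay below it. Of the counts of genes called, 60 stayed within 1.5 times and 111 did not, single libraries left out included. Of the values for lists and genes, 4457 kept their direction and side of the threshold, and 632 kept their direction but no longer passed. A further 237 passed where they had not, and 47 changed direction without passing in either fit or had no adjusted p. Of the 16 jejunal genes with the largest changes, 16 passed with DESeq2, 11 with edgeR and RLE, 9 with library totals and 8 with the length correction. Of the 16 liver genes, at least 14 passed in each setting that left no library out. At these depths a count of 0 allows up to 0.155 to 0.206 CPM, by library. On simulated data with 3 libraries per group limma recovered 10% of jejunal and 24% of liver genes changed by log2 1, and the parts of depth, spread and number of libraries in this were not tested apart.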

Other observations

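The genes below were chosen after their values were seen, and no test of a hypothesis was added. Values are normalized counts of wild-type libraries 1 to 3 and then antibiotics libraries 1 to 3.

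Markers of the ileum stood out in jejunal antibiotics library 3. Fabp6, the ileal bile acid binding protein, was at 79.9, 14.5, 81.7, 119, 14.4 and 9108. The bile acid transporter Slc10a2 was at 3.03, 0, 0, 4.52, 0 and 41.6, and the hormone gene Fgf19 at 0 in the first 5 libraries and 45.3 in the last.

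Cyp1a1, a target of the aryl hydrocarbon receptor, was at 938, 1161, 449.5, 30.5, 449.8 and 71.8 in jejunum (log2 fold change −2.96, limma adjusted p = 0.106). Another listed target of that receptor, Cyp1b1, rose in jejunum (2.36, limma adjusted p = 0.0392). In liver 2 other targets of that receptor rose, Tiparp by 1.86 and Nqo1 by 1.30 on the log2 scale, with adjusted p = 0.0459 and 0.0443. The list of its targets did not pass in liver (median 0.63, camera adjusted p = 0.344). The antimicrobial lectin genes Reg3b and Reg3g did not pass in jejunum. Reg3b was at 618.7, 446.6, 471, 1114, 222.8 and 668.2, and Reg3g at 695.6, 236.8, 440.9, 1323, 418.4 and 1067.

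Among liver receptors and transporters, Ppara rose by 1.96 on the log2 scale (adjusted p = 0.0225) and the monocarboxylate transporter Slc16a1 by 2.54 (adjusted p = 0.00996). The organic anion transporter Slco1a4 fell, with a log2 change of −1.75 (adjusted p = 0.0132). Abca3 rose by 2.68 and Abcc8 changed by −2.77 (adjusted p = 0.00888 and 0.00697).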
